A study of Populus tremula x Populus alba with 4 samples.

How the data were processed

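Messenger RNA of bark was profiled by paired-end RNA sequencing in 4 libraries of the hybrid poplar clone INRA 717-1B4 (Populus tremula x Populus alba), 2 from wild-type plants and 2 from plants transgenic for MIR15. Groups and replicate numbers were taken from the sample titles. The labels describe the 2 samples of each group as biological replicates and do not say whether the MIR15 samples came from separate transgenic lines. Per the file headers, the numbers in the deposited MIR15 columns differ from those in the sample titles, and the title numbers are used here.

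For each gene, the authors deposited 3 values. Per the file headers, the first is the count of unique gene reads and the second the count of total gene reads, both made with CLC. The third is a DESeq normalised signal per the file headers, and the submitters' processing notes also name DESeq, without a version. This signal was checked against the count columns and equals the total gene reads times 1 constant per library, from 0.898 to 1.10; the total reads were therefore what the authors normalised. The size factors this gives, 1.11 and 1.06 for wild type and 0.906 and 0.946 for MIR15, equal those that DESeq2 computed here from the same counts to the digits shown. The read aligner's settings, the genome build and the annotation version are not given in the sources used here. Each file lists the same 41335 transcript IDs, 1 transcript per gene, with an ID format that carries no gene name. How CLC placed reads that match more than 1 gene is not given in the sources used here, so genes with near-identical copies have uncertain totals.

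The total gene reads were tested with edgeR 4.0.16 in R 4.3.3, with its default filter on low counts (filterByExpr), TMM normalization and the quasi-likelihood F test, two-sided, with genotype as the sole term. Of the 41335 genes, 30975 were tested. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Levels are given in CPM, the read count scaled to the library total after TMM. The SE of a log2 fold change was derived from the F statistic. The median log2 fold change over all tested genes was under 0.01 in size, and no scaling alternative moved it by more than 0.02. Ratios of read sums are given with an exact 95% interval from the conditional binomial distribution, which covers counting error only.

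Before the data were examined, 33 gene lists, the rule for genes to be named, the tests and most alternative settings were fixed. The files pair no ID with a name and no annotation was used here, so 31 of the lists, which were name patterns, could not be filled. Among these were the markers of phloem, xylem, cambium, periderm and green tissue, and the list of RING-H2 proteins. The other 2 lists had been written as IDs, from general knowledge of the poplar gene models: 21 IDs for enzymes of monolignol synthesis and 5 IDs for cellulose synthases of the secondary wall. All 26 were in the files and passed the filter. Their membership was not checked against an annotation, so single members are given by ID alone. Lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 2 lists. The rule for named genes asked for called genes with a mean of at least 5 CPM and groups that do not overlap, for the list member with the smallest p where a list held no call, and for the 3 genes with most reads. No gene met its first part. Because the IDs carry no names, few are printed; those outside the rule are marked as chosen after their values were seen.

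The fit was tested on simulated data with the real means and library sizes, in which 200 of the tested genes were changed. The dispersion of each gene was drawn at random around the fitted trend, and genes were drawn independently. The counts below hold for that assumed spread. In this comparison of 2 against 2 libraries, edgeR recovered 2 of 50 genes changed 2-fold, 28 of 50 changed 4-fold, 42 of 50 changed 16-fold and 47 of 50 changed 64-fold, with 4 false calls among 123. DESeq2 1.42.0 recovered 19, 42, 47 and 50 of these, with 111 false calls among 269.

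Alternatives were RLE size factors, library size alone, no filter, a filter at a mean of 5 CPM, the replicate number as a block, leaving out each library, DESeq2, a test against a fold of 1.5, an adjusted p of 0.01, and an estimated correlation for the lists. The test on unique gene reads was added after seeing the data. Pseudocount alternatives did not apply, because counts were deposited. Library totals were between 68453851 and 82789893 reads. With 2 libraries per group, p-values rest on a spread estimated from 2 pairs of libraries.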

Results

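The series asked how transcript levels in the bark of MIR15 transgenic poplar differ from those of wild type. Bark comprises the tissues outside the vascular cambium, among them the phloem with its fibres and the periderm. The clone, INRA 717-1B4, is a hybrid poplar widely used for genetic transformation. The labels name no gene that the MIR15 construct is meant to lower, so no target could be examined. Total gene reads came to 82789893 and 77052567 in wild-type replicates 1 and 2, and to 68453851 and 69747662 in MIR15 replicates 1 and 2. At least 1 read was counted for 34991 and 34935 genes in wild type, and for 34452 and 34559 genes in MIR15.

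The 3 genes with most reads were Potri.005G133100.1, Potri.004G015300.1 and Potri.006G130900.1. Potri.005G133100.1 took 2.30% and 2.47% of all reads in the wild-type libraries, and 1.34% and 1.52% in the MIR15 libraries. Of its reads, 96.2% matched more than 1 place. Its level was 23687 ± 873 CPM (SD, n = 2) in wild type and 14371 ± 1031 CPM (SD, n = 2) in MIR15, a log2 fold change of -0.72 ± 0.29 (SE) that did not pass the edgeR quasi-likelihood test (adjusted p = 1.00). DESeq2 gave it an adjusted p of 0.0490. In unique reads its log2 fold change was 0.07, and there the wild-type libraries disagreed, with 1125 and 398 CPM against 737 and 861 CPM in MIR15: the value was 1.00 without wild-type replicate 1 and -0.49 without wild-type replicate 2. Potri.004G015300.1 had 7524 ± 676 CPM in wild type and 8719 ± 1357 CPM in MIR15 (SD, n = 2 each), with an adjusted p of 1.00 from edgeR. Potri.006G130900.1 had 2355 ± 189 and 2474 ± 129 CPM (SD, n = 2 each), also with an adjusted p of 1.00 from edgeR.

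The libraries of one genotype differed from each other about as much as those of different genotypes. Over the 25931 genes with a mean of at least 1 CPM, the root-mean-square log2 difference was 0.42 between the wild-type libraries and 0.43 between the MIR15 libraries. Across genotypes it lay between 0.34, for wild-type replicate 1 against MIR15 replicate 1, and 0.49, for wild-type replicate 2 against MIR15 replicate 1. Between the wild-type libraries, 899 genes differed more than 2-fold, and between the MIR15 libraries 826 did. No pair of libraries agreed within sampling noise, so all 4 were kept as separate samples.

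In MIR15 bark, 1 of 30975 tested genes changed. Potri.003G037700.1 fell from 6.39 ± 0.0656 CPM in wild type to 0.0509 ± 0.00886 CPM in MIR15 (SD, n = 2 each). It had 523 and 505 reads in the wild-type libraries, and 3 and 4 reads in the MIR15 libraries. The ratio of wild type to MIR15 was 127, with an exact 95% counting interval from 61.4 to 317. Its log2 fold change was -6.92 ± 0.38 (SE), with an adjusted p of 0.00749 in edgeR's quasi-likelihood test. The gene lies below the level set beforehand for genes to be named and was chosen after its values were seen. Of its reads, 65.7% matched more than 1 place. In unique reads alone it had 158 and 194 reads in wild type and 1 and 2 in MIR15, a log2 fold change of -6.54, but the adjusted p from edgeR was then 0.138. The call was also lost without MIR15 replicate 1 (edgeR adjusted p = 0.248) and without MIR15 replicate 2 (edgeR adjusted p = 0.154), where the fold was -6.77 and -7.11 on the log2 scale. With DESeq2, the adjusted p was 3.41e-24.

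No gene rose past the threshold of the edgeR test. At an unadjusted p under 0.05, edgeR gave 419 higher and 345 lower genes, 764 in all or 2.47% of those tested. That is below the share of 0.05 that would pass by chance if no gene differed. In 25.1% of tested genes the MIR15 libraries did not overlap the wild-type libraries, where chance gives 33.3% for 2 against 2. Both comparisons with chance assume that nothing else sets the libraries apart. Dividing them by title number instead gave 2875 genes at an unadjusted p under 0.05 in edgeR. The low shares therefore do not show that genotype has no effect. DESeq2 called 14 genes, 8 higher and 6 lower, and Potri.003G037700.1 was among them. The higher genes with the smallest p in DESeq2, chosen after their values were seen, were Potri.001G051000.1 and Potri.017G060400.1. Potri.001G051000.1 had 0.780 ± 0.184 CPM in wild type and 3.84 ± 0.725 CPM in MIR15 (SD, n = 2 each), a log2 fold change of 2.30 ± 0.34 (SE), with an adjusted p of 2.96e-05 in DESeq2 and 1.00 in edgeR. Potri.017G060400.1 had 7.74 ± 0.468 CPM in wild type and 16.4 ± 0.595 CPM in MIR15 (SD, n = 2 each), a log2 fold change of 1.09 ± 0.17 (SE), with an adjusted p of 0.00138 in DESeq2 and 1.00 in edgeR. None of the reads of these 2 genes matched more than 1 place. After Potri.003G037700.1, the lower gene with the smallest p in DESeq2 was Potri.014G186000.1, also chosen after its values were seen. It had 478.4 ± 92.6 CPM in wild type and 179 ± 3.41 CPM in MIR15 (SD, n = 2 each), a log2 fold change of -1.42 ± 0.19 (SE), with an adjusted p of 4.68e-08 in DESeq2 and 1.00 in edgeR (0.0431 without wild-type replicate 1). Of its reads, 84.9% matched more than 1 place, and in unique reads its log2 fold change was -0.63 (edgeR adjusted p = 1.00). That fold change was -0.32 without wild-type replicate 1 and -0.89 without wild-type replicate 2.

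**Figure D1:**
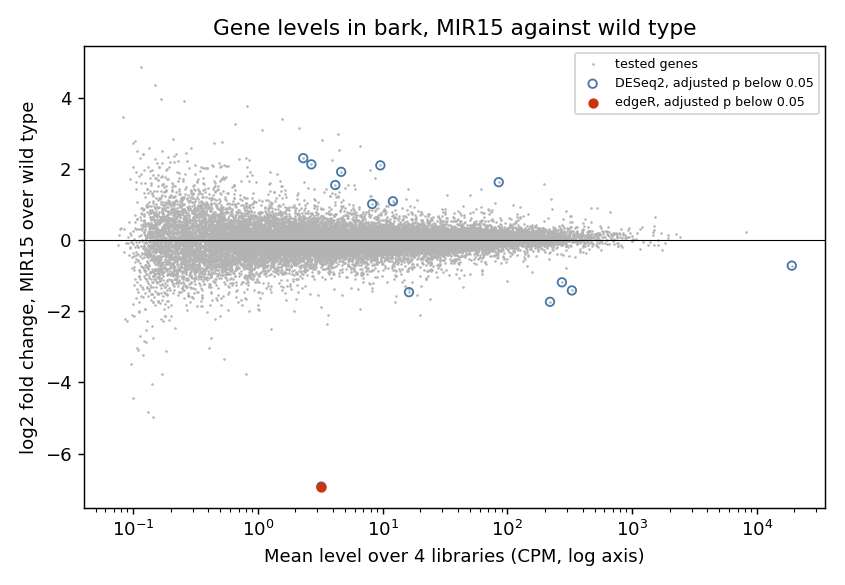
Each grey point is 1 of the 30975 genes tested in edgeR, with its mean CPM over the 4 libraries on a log axis and its log2 fold change of MIR15 over wild type. The filled point is Potri.003G037700.1, the single gene called by edgeR, at -6.92; open circles are the genes called by DESeq2.

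Genes listed beforehand for monolignol synthesis, the pathway that supplies the building blocks of lignin, were expressed in bark of both genotypes, and none of the 21 passed the test. Their mean levels ran from 9.13 CPM to 2253 CPM. Their log2 fold changes lay between -0.20 and 0.17, with 10 values above 0 and 11 below, and a median of -0.02. Adjusted over the list alone, 0 of 21 passed, with a smallest adjusted p of 0.970 in edgeR, and 0 had an unadjusted p under 0.05. The member with the smallest p, Potri.001G175000.1, had 20.2 ± 0.488 CPM in wild type and 17.6 ± 0.324 CPM in MIR15 (SD, n = 2 each), with an unadjusted p of 0.236 in edgeR. Camera gave the list an adjusted p of 0.875, and of 0.965 with an estimated correlation; fry's adjusted p was 0.963 for one direction and 0.946 for either. The libraries of each genotype differed within this list: in wild type, 19 of 21 members were higher in replicate 1 than in replicate 2, by a median of 1.24-fold, and in MIR15, 16 of 21 were, by 1.17-fold. Without MIR15 replicate 2 the median turned to 0.09, with 16 of 21 values above 0, and without MIR15 replicate 1 it was -0.12, with 17 of 21 below 0 (camera adjusted p = 0.411 and 0.217). Measured without wild-type replicate 1, the list had a median log2 fold change of 0.15, with 17 of 21 values above 0 and a camera adjusted p of 0.0141 (adjusted p = 0.435 with an estimated correlation). Without wild-type replicate 2 the median was -0.17, with 19 of 21 values below 0 and a camera adjusted p of 4.56e-04 (adjusted p = 0.390 with an estimated correlation).

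The 5 listed cellulose synthase genes of the secondary wall had mean levels from 32.8 to 160 CPM and also showed no call. Their log2 fold changes ran from -0.04 to 0.07, with 4 values above 0, 1 below and a median of 0.04. None passed adjusted over the list alone, where the smallest edgeR adjusted p was 0.874, and 0 had an unadjusted p under 0.05. The member with the smallest p, Potri.018G103900.1, had 98.9 ± 21.9 CPM in wild type and 104 ± 0.551 CPM in MIR15 (SD, n = 2 each). Camera gave the list an adjusted p of 0.875, and of 0.965 with an estimated correlation; fry's adjusted p was 0.963 for one direction and 0.946 for either. All 5 were higher in wild-type replicate 1 than in replicate 2, by a median of 1.38-fold, and both MIR15 libraries lay between them at the median. Without wild-type replicate 1 the median log2 fold change was 0.31, with a camera adjusted p of 0.0141 (adjusted p = 0.435 with an estimated correlation). Without wild-type replicate 2 it was -0.20, with a camera adjusted p of 0.0180 (adjusted p = 0.390 with an estimated correlation).

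**Figure D2:**
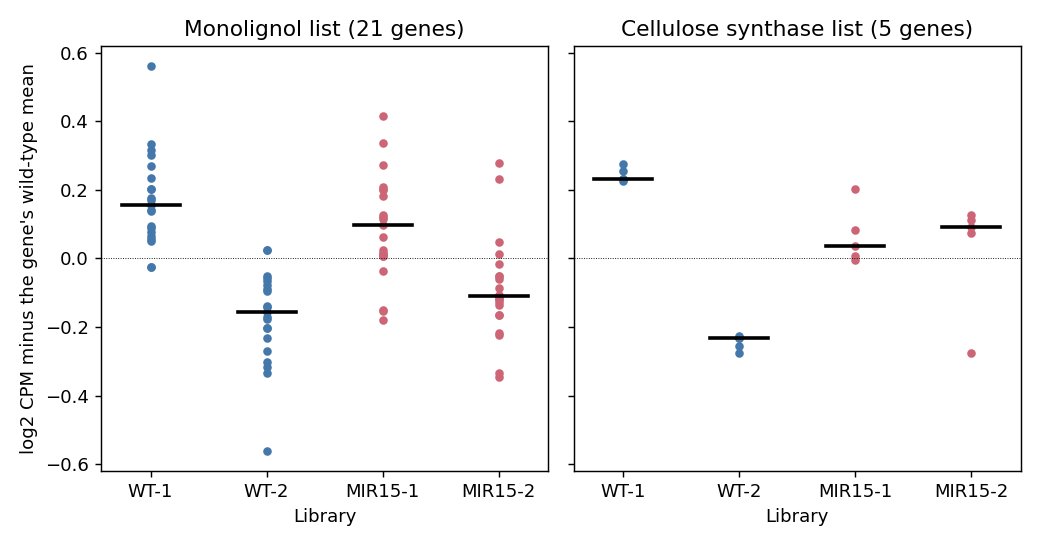
Each point is a listed gene in 1 library, as log2 CPM minus the gene's mean over the wild-type libraries; bars are the medians over the 21 monolignol genes (left) and the 5 cellulose synthase genes (right). The medians of the wild-type libraries stand apart, at 0.16 and -0.16 in the left panel and at 0.23 and -0.23 in the right panel, and those of the MIR15 libraries lie between them.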

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

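Against 1 called gene in the edgeR fit, the count was 14 with DESeq2, 0 in unique reads, and 0 with the filter at a mean of 5 CPM, which removes Potri.003G037700.1 by construction. At these counts of 0, edgeR gave 768 of 30531 and 389 of 20097 tested genes with an unadjusted p under 0.05. Leaving out single libraries gave 0 to 8 genes: 8 without wild-type replicate 1, and 0 without either MIR15 replicate, where 882 (without replicate 1) and 1351 (without replicate 2) genes had an unadjusted p under 0.05; the lone sample of a group is then assumed to vary like the other group. These counts at an unadjusted p under 0.05, from the settings with 0 calls, lie below the share of 0.05 that chance alone would give. The share lay above 0.05 without wild-type replicate 1, and slightly above it with the title number as a replicate block (1558 of 30975). RLE factors, library size alone, no filter, a fold of 1.5 and an adjusted p of 0.01 each called the same single gene. With the title number as a replicate block, edgeR called 120 genes, 69 higher and 51 lower, of which 13 were among the 14 called by DESeq2; Potri.001G051000.1, Potri.017G060400.1 and Potri.014G186000.1 were among these (edgeR adjusted p = 0.00175, 0.00603 and 1.40e-04). The block fit leaned more on the spread shared over all genes (edgeR prior degrees of freedom 27.9, against 5.28 in the main fit). Libraries with the same number deviated together (correlation of deviations 0.25), but no label says that the number marks a shared origin. There are also only 2 pairs, so the numbers were not taken to pair the samples. The monolignol list's median was -0.02 in the main fit; its direction by camera turned with the replicate block (median -0.0065), and leaving out single libraries gave medians from -0.17 to 0.15. The cellulose synthase list's median went from -0.20 to 0.31 when single libraries were left out. The monolignol list's direction turned without wild-type replicate 1 and without MIR15 replicate 2, and that of the cellulose synthase list without wild-type replicate 2; the cause was not tested. The camera calls, all made without 1 of the wild-type libraries, are lost with an estimated correlation. Potri.005G133100.1 turned from -0.72 to 0.0686 on the log2 scale in unique reads, where the wild-type libraries differed more than 2-fold and the sign depends on which of them is kept. When single libraries were left out, Potri.006G130900.1 went from -0.00705 to 0.158 and Potri.018G103900.1 from -0.137 to 0.316; edgeR called none of these in any of those settings. On simulated data with 2 libraries per group at these read totals, edgeR recovered 2 of 50 genes changed 2-fold and 28 of 50 changed 4-fold; neither depth nor the number of libraries was varied.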

Other observations

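The test on the neighbours of Potri.003G037700.1 and the count over other splits of the libraries were set out before their results were seen; the other tests here were chosen after. Most IDs in the files hold a 3-digit prefix and a number, and the description that follows orders these genes by that number, on the assumption that it follows their order along a chromosome; IDs with a T in place of the prefix were left out. Under the prefix Potri.013G, 47 consecutive genes with a mean of at least 1 CPM, from number 135600 to 143400, had lower mean values in MIR15 than in wild type, with a median log2 difference of -0.78 and an SD over genes of 0.29. The next longest such run in the data had 17 genes, and the longest in 1000 shuffles of the gene order had 26. Within a genotype, the longest run with replicate 2 below replicate 1 had 27 genes in MIR15 and 13 in wild type. Runs with replicate 1 below replicate 2 were not counted, though most genes of this block go that way in MIR15. The run of 47 therefore lacks a full comparison within a genotype. In 37 of the 47 genes under Potri.013G, both MIR15 libraries lay below both wild-type libraries. Relative to the wild-type mean, the median was 47.2% in MIR15 replicate 1 and 73.8% in MIR15 replicate 2, and 38 of the 47 genes were lower in replicate 1. No gene of the block was called by edgeR, 25 had an unadjusted p under 0.05, and 6 were called with the replicate block. In 44.7% of the block's genes, at least 5% of reads matched more than 1 place, against 13.9% of all genes scanned. The run was found by its values, so that all its genes are lower is a matter of its definition.

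In a scan of 25061 genes with windows of 19 neighbours, the most extreme median of MIR15 minus wild type was -0.92, in this block. The largest in 1000 shuffles of the gene order was 0.36 (permutation p = 0.000999, the smallest these shuffles can give); neighbouring genes are not independent, and the shuffles say nothing of the spread between plants. Of 8 stretches beyond the 95th percentile of the shuffles, the others with lower values were at Potri.003G206400 to 210000 (-0.50), Potri.011G072500 to 076500 (-0.50), Potri.014G182000 to 187000 (-0.53), Potri.019G025400 to 028700 (-0.38) and Potri.005G131600 to 134500 (-0.29). Those with higher values were at Potri.016G014600 to 017400 (0.51) and Potri.006G018000 to 020500 (0.41). Such stretches were not limited to the genotype contrast: 9 were found between the MIR15 libraries and 1 between the wild-type libraries. The cut-off came from each comparison's own shuffles, so these counts are not on the same scale. It was 0.27 for genotype, 0.45 between the MIR15 libraries and 0.43 between the wild-type libraries. The stretch under Potri.014G reached -0.92 in MIR15 replicate 2 and was not found in MIR15 replicate 1 against wild type.

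A hypothesis for the block under Potri.013G is the loss of 1 of 2 gene copies in the MIR15 plants, which would bring both libraries near -1 on the log2 scale. The median of MIR15 replicate 1 was -1.08, inside the range of -1.3 to -0.7 set for that cause after the block was found. That of MIR15 replicate 2 was -0.44, outside the range. This argues against an equal loss in both samples only if levels follow copy number and plants vary little, and neither was tested. A loss in replicate 1 alone, or one carried by part of the tissue, was not tested. Reads shared with copies elsewhere are argued against as the whole cause. The 26 block genes with under 5% of such reads had a median of -0.79 (SD 0.30). That these genes lie below 0 follows from how the run was found, but the size of their median does not. Spread between libraries of a genotype cannot be told apart from an effect of genotype with 2 libraries each, because the MIR15 libraries differed by a window median of 0.89 in the same block, the largest within a genotype; the largest between single MIR15 libraries and the wild-type mean was 1.28 in size, also in this block, and the largest between the wild-type libraries was 0.56, under Potri.017G. Genotype itself, and joint regulation of neighbouring genes of like function, stay open and could not be examined without an annotation.

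Among the genes passing the rule below, Potri.003G037700.1 stood alone in the size of its loss. The rule was made after the gene was seen, and its upper limit of 4 reads is this gene's own highest count in MIR15. Genes with more reads in the lower group are left out, so the rule cannot show that no other gene fell as much. Under the rule of at least 20 reads in both libraries of one group and at most 4 in both of the other, 6 genes were on in wild type and 1 in MIR15; dividing the libraries by title number gave 5 and 2 genes, and the crossed division gave 5 and 1. The lower of the on libraries had 505 reads for Potri.003G037700.1, against at most 38 and 30 reads for any gene in these other divisions. A wider loss around it is argued against by the 10 nearest tested IDs, whose median log2 fold change was -0.13 (SD 0.15). Reads moving to near-identical copies are argued against by its log2 fold change of -6.54 in unique reads. Silencing through the transgene, disruption of the gene itself and a difference between the plants sampled may each account for the loss, and no value here separates them.

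The 4 libraries allow only 3 divisions into 2 and 2, too few for a share under 0.05. Of these, 2 called at least 1 gene in edgeR: the real one with 1 and the division by title number with 2, the highest of the others. With DESeq2, the division by title number called 475 genes, against 14 for genotype and 5 for the crossed division. At an unadjusted p under 0.05, edgeR gave 764 genes for genotype, 1022 for the crossed division and 2875 for the division by title number. DESeq2 made 111 false calls among 269 in the simulation, under the spread assumed there. For genotype it called 14 genes in all in the real data, so that spread may not hold here. What share of its real calls is false was not tested, and its counts are given with that limit. A structure of the samples other than genotype may lie behind these counts, and what would set it apart is not given in the labels. By the numbers of the deposited columns, 2 and 3 for MIR15, MIR15 replicate 1 would instead share a number with wild-type replicate 2. That pair differed most (root-mean-square log2 difference 0.49). The division by title number and the replicate block therefore both rest on the title numbers.

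The share of reads that matched more than 1 place was 6.46% and 6.17% in wild type, and 5.29% and 5.72% in MIR15. Without Potri.005G133100.1, the shares were 4.37% and 3.83% in wild type and 4.07% and 4.35% in MIR15, and the groups overlapped.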
